A study of Mus musculus with 6 samples.

How the data were processed

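Total RNA from sorted elongating spermatids was extracted with Trizol, amplified and labelled with a 3' IVT kit and hybridised to Affymetrix mouse arrays, per the labels' protocols. The deposited table holds 1 signal intensity per probe set and array, on a linear scale, for 45101 probe sets and 6 arrays. The submitters' processing notes name MAS5, the Affymetrix summary that combines perfect-match and mismatch probes, and no version or genome build is given in the sources used here. The values show that the authors' deposited intensities were scaled to a 2% trimmed mean of 500 on every array, so that an array with few bright probe sets is multiplied up. Detection calls and scanner files were not used here. Groups and replicate numbers were taken from the sample titles.

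Signals were taken to log2 after adding 16, so fold changes of dim probe sets are understated. The 64 Affymetrix control probe sets were left out, and probe sets with a mean log2 above the 40th percentile were kept, which left 27022. Of these, 23660 name 1 gene, 672 several and 2690 none in the platform annotation, and genes were named only from the first kind. Symbols were compared through the gene identifiers with the mouse RefSeq table (assembly GRCm38.p6), which matched 99.4% of them and changed 0, and no coordinates are given. Where a gene has several probe sets, the one with the highest mean over all arrays stood for it, which gave 14298 genes. That mean includes the control arrays, so a probe set bright only on these can stand for a gene and favours a fall against control. The filter also used the mean over all arrays, so a probe set bright only on the control arrays could pass it. Values of named genes are of that probe set unless stated, and others of the same gene can differ.

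Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) in 1 model of 3 group means over all 6 arrays, with 3 residual degrees of freedom, and Benjamini-Hochberg adjustment over the tested probe sets; calls are at an adjusted p under 0.05. The 3 groups share 1 estimate of the spread, although the control arrays varied far more than the others. The fit on the 4 shRNA arrays alone (2 residual degrees of freedom) was a second analysis, set before the data were examined. The labels call the replicates biological, and no source used here says how many animals or testes each array stands for. A size rule without a p-value counted probe sets at least 2-fold apart with no overlap of the groups. Chance gives no overlap to 33.3% of probe sets if all 4 arrays vary alike, which the wider spread of the control arrays contradicts. Gene lists, 25 in number, were tested with camera at a preset correlation of 0.01 and with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison; the erythrocyte list had only 2 members and was not tested. Arrays were also rescaled on 18 hybridization control probe sets (bioB, bioC, bioD and cre).

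Other added constants, filters, scalings (quantile, median and hybridization controls), variance models, thresholds, choices of probe set, a block for the replicate number and leaving out each array were also run. The lists, the tests and the rule for named genes were fixed before the data were examined, apart from camera on the 4 shRNA arrays. So were these alternatives, apart from those for the 4 arrays, hybridization scaling of lists and separate controls for the correlation. The rule takes Piwil1, Cnot7 and Cnot8, the 8 largest rises and falls against control, the 4 largest between the shRNA groups, and up to 4 members of each list. It named 106 genes for shMiwi and 104 for shCaf1 against control. After values had been seen, the text was limited to genes among the 4 largest per direction and the first 2 per list, which are 54 and 55 genes. Of the rule's genes, 47 and 45 were lower than control, and 31 and 28 of these turned higher on the hybridization scale; within the subset the numbers are 23 and 22 lower, and 13 and 11 turning. A few genes outside the rule are marked as chosen after their values were seen.

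The limma calls for shMiwi against control and for shMiwi against shCaf1 were tested on simulated data with 100 probe sets changed 2-fold and 100 changed 4-fold, and camera on simulated lists; shCaf1 against control and the size rule were not simulated. With the spread of each group as observed, shMiwi against control recovered 35% of the 4-fold and 3% of the 2-fold changes among 27022 probe sets, and 447 of its 485 calls were false. The 4-array fit recovered 29% and 3% with 0 false calls, and the 6-array fit of shMiwi against shCaf1 made 0 calls. With an equal spread in all groups, shMiwi against control recovered 58% and 14% with 0 false calls.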

Results

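Gene expression was measured on Affymetrix mouse 3' arrays in sorted mouse elongating spermatids, the cells that follow meiosis in which the nucleus condenses. Testes of ICR mice, an outbred strain, had been transduced at 5 weeks of age with lentiviral vectors that carry GFP, and GFP-positive elongating spermatids were sorted 1 week later. The vectors were an empty control (pSilencer), a short hairpin RNA named for Miwi (shMiwi) and a short hairpin RNA named for Caf1 (shCaf1). Miwi is the mouse PIWI protein Piwil1, which binds piRNAs in spermatocytes and spermatids, and Caf1 is taken here to be the deadenylase Cnot7, a catalytic subunit of the CCR4-NOT complex that shortens poly(A) tails. Each of the 3 groups held 2 arrays, labelled as biological replicates, and this number limits the precision of every value. The question addressed was which transcripts differ in spermatids when either factor is targeted.

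The 2 control arrays stood apart from the 4 shRNA arrays, and from each other, on control probe sets and on array-wide measures. The array-wide measures include the targeted genes. The signal of the hybridization controls, biotin-labelled RNAs added in a fixed amount before hybridization, was 82.3-fold the mean of the shRNA arrays on control 1 and 16.2-fold on control 2. It was 1.10-fold and 1.20-fold on the shCaf1 arrays and 0.941-fold and 0.806-fold on the shMiwi arrays. The deposited values had the same trimmed mean of 500 on every array. After scaling on the hybridization controls, 101 probe sets exceeded a signal of 1000 on control 1, 495 on control 2, and between 5980 and 8137 on the shRNA arrays. The 100 brightest probe sets held 52.6% of the summed signal on control 1, 29.5% on control 2, and between 5.85% and 7.25% on the shRNA arrays. Across the 27022 tested probe sets, Pearson's r was 0.451 between the control arrays, 0.983 between the shCaf1 arrays and 0.982 between the shMiwi arrays. Control 1 correlated with the shRNA arrays at r between 0.04 and 0.07, control 2 at r between 0.40 and 0.46, and the shCaf1 with the shMiwi arrays at r between 0.968 and 0.974. The 3' to 5' signal ratio, a measure of RNA integrity and amplification, was 0.691 for Actb and 0.723 for Gapdh on control 1, 14.5 and 5.11 on control 2, and between 2.05 and 4.69 and between 0.811 and 1.73 on the shRNA arrays. The correlations are across probe sets, which are not independent replicates. The median absolute difference between replicates was 1.28 on the log2 scale for control, 0.185 for shCaf1 and 0.218 for shMiwi. Values against control are on the deposited scale unless the scale of the hybridization controls is named.

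**Figure D1:**
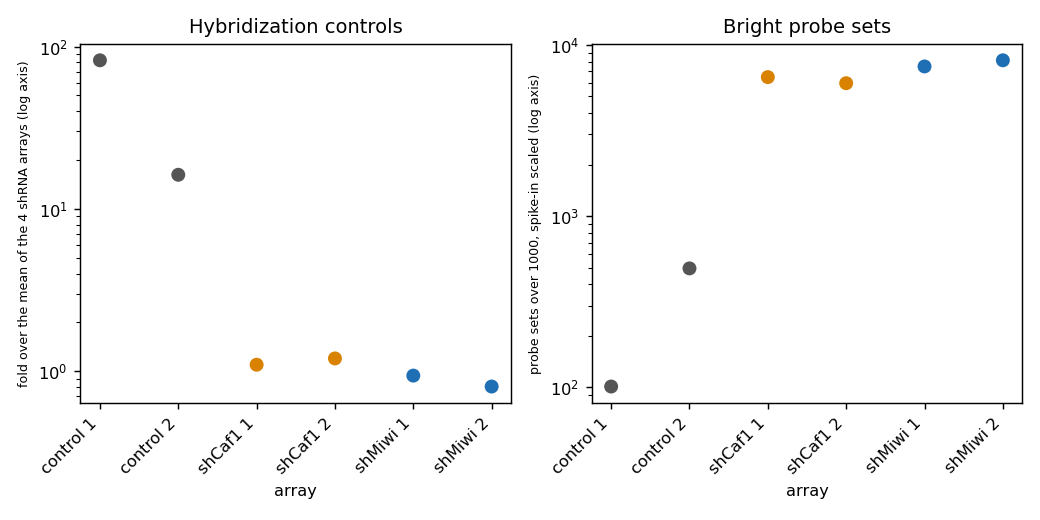
Signal of the hybridization controls as a fold over the mean of the 4 shRNA arrays (left) and number of probe sets over a signal of 1000 after scaling on those controls (right), 1 point per array, log axes. Control 1 lies at 82.3-fold and 101 probe sets and control 2 at 16.2-fold and 495, apart from the shCaf1 and shMiwi arrays.

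The targeted genes were examined first. The Piwil1 probe set read 9780 and 10392 on the shMiwi arrays, 21881 and 22442 on the shCaf1 arrays, and 1445360 and 292542 on the control arrays. Piwil1 was lower in shMiwi than in control by a log2 difference of -6.01 (SE 0.85, n = 2 per group, limma adjusted p = 0.00675) on the deposited scale. On the scale of the hybridization controls that difference was -0.62 and did not pass (adjusted p = 0.759), with signals of 17566 and 18023 in control against 10391 and 12893 in shMiwi. Piwil1 was also lower in shCaf1 than in control on the deposited scale, by -4.87 (SE 0.85, adjusted p = 0.0111), and the sign turned to 0.12 on the hybridization scale. Between the shRNA groups, Piwil1 was lower in shMiwi by -1.14 (SE 0.09, adjusted p = 0.00105 in limma on the 4 shRNA arrays), and by -0.74 on the hybridization scale. In the limma fit on all 6 arrays the same difference had an SE of 0.85 and did not pass. Without shMiwi replicate 1 or replicate 2 the call of Piwil1 against control was lost (adjusted p = 0.0653 and 0.0766), as was its call in shCaf1 without either shCaf1 array (adjusted p = 0.0838 and 0.0884).

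The Cnot7 probe set with the highest mean signal read 3633 and 4330 on the shCaf1 arrays, 4365 and 5012 on the shMiwi arrays, and 2003570 and 188877 on the control arrays. Cnot7 was lower than control by -7.27 in shCaf1 (SE 1.14, limma adjusted p = 0.00886) and by -7.03 in shMiwi (SE 1.14, adjusted p = 0.00854). On the hybridization scale the differences were -2.28 (adjusted p = 0.147) and -1.65 (adjusted p = 0.276). Between the shRNA groups Cnot7 differed by 0.24 (SE 0.13, adjusted p = 0.307 in limma on the 4 arrays). On the hybridization scale it differed by 0.63 and passed as higher in shMiwi (adjusted p = 0.0134). That scale moved the median of all probe sets from 0.02 to 0.38, so part of the 0.63 is a shift common to all. In the 4 arrays another Cnot7 probe set was higher in shMiwi by 0.73 (adjusted p = 0.032). The remaining Cnot7 probe set, at 0.38, did not pass (adjusted p = 0.264). Cnot8, the closely related deadenylase, rose against control by 2.33 in shCaf1 (SE 0.42, adjusted p = 0.0116) and by 2.41 in shMiwi (adjusted p = 0.00991). Its other probe set showed 0.62 and 0.73, which did not pass (adjusted p = 0.386 and 0.313). The Cnot7 calls were lost without either array of the group compared (adjusted p = 0.0769 and 0.0807 in shCaf1, 0.0691 and 0.0787 in shMiwi). The lower Piwil1 signal in shMiwi passed against shCaf1 in the 4 arrays, though not with eBayes without an intensity trend (adjusted p = 0.133), while neither target passed against control on both scales. Among the 100 brightest probe sets of control 1, most others also read lower in shMiwi than in shCaf1, many of them by less than Piwil1. Acp1 read 285 and 274 against 1009 and 799, and Rpl27a 298 and 319 against 884 and 919. Dhx15 was in the minority that read higher, at 8371 and 9431 against 7125 and 6508. A fall of this size was thus not particular to Piwil1.

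**Figure D2:**
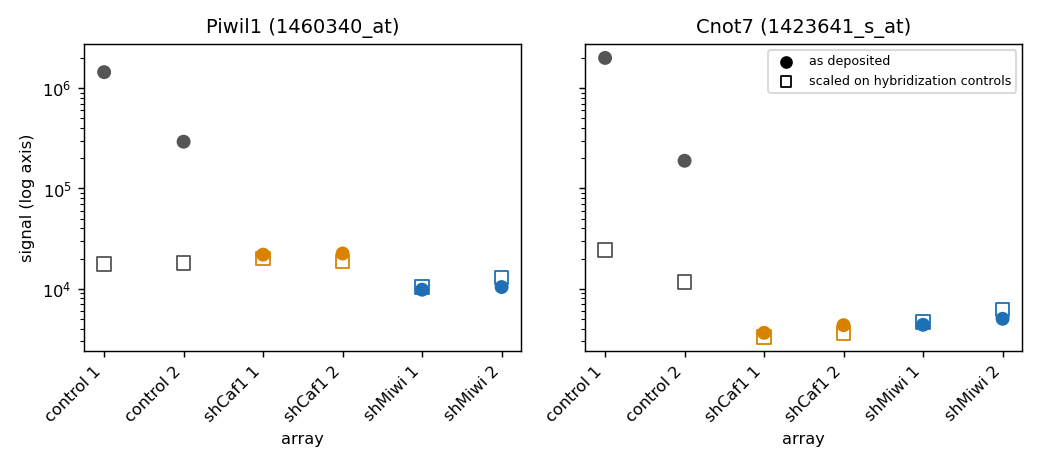
Signal of Piwil1 and Cnot7 on each array (log axis), as deposited (filled circles) and scaled on the hybridization controls (open squares). Piwil1 after scaling is 17566 and 18023 in control and 10391 and 12893 in shMiwi, while the deposited control signals are 1445360 and 292542.

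For shMiwi against control, the largest rises included germ cell genes. Pdcl2, a phosducin-like gene of germ cells, rose by a log2 difference of 7.81 (SE 0.92, adjusted p = 0.00529, n = 2 per group), Ccdc39, an axonemal assembly factor, by 7.55 (SE 0.33) and Dazl, a germ cell RNA-binding protein, by 7.498 (SE 0.38), the last pair at adjusted p = 0.00374. Ccdc39 read 22 and 21 on the control arrays (percentiles 2.23 and 8.42) against 6785 and 7185 on the shMiwi arrays. The size of a rise from such a dim signal depends on the background and on the added constant of 16. The largest falls were Dus2 at -9.82 (SE 0.44), Hoxa5, a homeobox transcription factor, at -8.72 (SE 0.37) and Acp1 at -8.21 (SE 0.66), and these kept their sign on the hybridization scale at -4.58, -3.39 and -2.84. Other probe sets of Acp1 rose by 1.25 (adjusted p = 0.0384) and 2.93 (adjusted p = 0.00928), and another of Dus2 did not pass (-0.82, adjusted p = 0.367).

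Of the 22 piRNA pathway genes, 14 rose and 1 fell in shMiwi (15 and 1 adjusted over the list alone), with a median log2 difference of 3.08 (SD 2.53 over genes). Ddx4, the germ cell helicase Vasa, rose by 6.25 (SE 1.31, adjusted p = 0.0163), and the gene that fell was Piwil1. The list was higher than other genes by camera with a preset correlation (adjusted p = 0.000200), a call lost with an estimated correlation (adjusted p = 0.151). Of 35 pachytene spermatocyte genes, 20 rose and 2 fell (22 and 2 adjusted over the list alone), among them the synaptonemal complex genes Sycp3 at 6.502 (SE 1.05) and Sycp2 at 6.29 (SE 0.68). Of 34 round spermatid genes, 13 rose and 0 fell (12 and 0 adjusted over the list alone), with the acrosomal genes Spaca1 at 5.999 (SE 1.08) and Zpbp at 5.92 (SE 0.90). The camera calls for pachytene genes (adjusted p = 8.65e-05) and round spermatid genes (adjusted p = 0.000200) were lost with an estimated correlation (adjusted p = 0.151 and 0.688). Of 74 axoneme genes, 36 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 9.95e-07, and adjusted p = 0.151 with an estimated correlation), and Cfap43 rose by 6.77 (SE 0.34). Of 40 chaperone genes, 17 rose and 3 fell (19 and 3 adjusted over the list alone; camera adjusted p = 0.000449, and adjusted p = 0.467 with an estimated correlation), led by Hspa4 at 6.81 (SE 0.47). Of 156 ubiquitin ligase and conjugation genes, 45 rose and 19 fell, also adjusted over the list alone (camera adjusted p = 0.0307, and adjusted p = 0.151 with an estimated correlation), with Ube2u at 5.87 (SE 0.57).

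Of the 32 elongating spermatid genes, the stage that was sorted, 2 rose and 2 fell in shMiwi (0 and 1 adjusted over the list alone), and camera did not pass (adjusted p = 0.12). Fam71b rose by 3.596 (SE 0.91, adjusted p = 0.0275) and Car4 fell by 3.34 (SE 0.50, adjusted p = 0.00739), with a turn to 1.18 on the hybridization scale. The median percentile of this list within an array was 45.6 on control 1, 98.0 on control 2 and between 97.8 and 99.1 on the shRNA arrays. Relative to the median gene, the list was 3.90 higher in shMiwi than on control 1 and 0.80 lower than on control 2 (log2 value -0.80). The round spermatid list was 4.43 and 1.21 higher, the pachytene list 3.22 and 2.87, and the piRNA pathway list 2.63 and 2.93, than on control 1 and control 2. Among lists of other cell types in the testis, Sertoli cell genes lay at a median percentile of 68.2 on control 1, 91.2 on control 2 and between 82.7 and 86.4 on the shRNA arrays, and endothelial genes at 87.9, 79.1 and between 59.9 and 64.1.

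Ribosomal protein genes were lower in shMiwi on the deposited scale, with 16 of 47 fallen and 3 risen (15 and 3 adjusted over the list alone; camera adjusted p = 0.0474, and adjusted p = 0.468 with an estimated correlation). Rps19 fell by 6.57 (SE 0.61; -1.19 on the hybridization scale), and 11 of the 16 falls in the list turned to a rise on the hybridization scale. Of 22 CCR4-NOT and deadenylation genes, 4 rose and 8 fell (4 and 9 adjusted over the list alone; camera adjusted p = 0.419), and Cnot2 fell by 5.25 (SE 0.37) but stood at 0.12 on the hybridization scale. Among 37 decapping and decay genes 7 rose and 8 fell (7 and 8 adjusted over the list alone), with Dis3 at 4.56 (SE 0.76) and Ddx6 at 4.16 (SE 0.72). All 6 interferon response genes that fell, of 16 tested, and all 4 endothelial genes that fell, of 8, turned to a rise on the hybridization scale, as did 96.5% of all lower calls (6 and 4 also adjusted over the list alone), and neither list passed camera (adjusted p = 0.0556 and 0.0692). Of 21 glycolysis genes 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0738).

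In total, limma called 11687 of 27022 probe sets in shMiwi against control, 4559 higher and 7128 lower, from 7653 named genes. The split became 5510 higher and 4024 lower with quantile normalization, 5801 and 5858 with each array centred on its median, and 25397 and 24 with hybridization control scaling, which moved the median difference of all probe sets from -0.20 to 3.58. That shift moved all probe sets the same way, so no higher call could turn. Of the lower calls, 96.5% turned higher, and 99 stayed lower than each control array on both scales. Without control replicate 1 the count was 21538, without control replicate 2 it was 22700, without shCaf1 replicate 1 or 2 it was 6664 or 6658, and without either shMiwi array it was 0. By size alone, 16838 probe sets were at least 2-fold apart with no overlap, against 2285 and 2845 in the other splits of the same 4 arrays into pairs. The shMiwi arrays lay close together (median difference 0.218) and the controls far apart (1.28). The other splits are thus no measure of chance. In data simulated with each group's own spread, 447 of 485 calls in this comparison were false. The shared estimate of spread is thus too small for the control arrays, and the adjusted p-values against control are too low. Only 100 probe sets were changed 2-fold and 100 4-fold there, so that share of false calls does not carry over to the 11687 calls.

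For shCaf1 against control, Pdcl2 rose by 7.997 (SE 0.92, adjusted p = 0.00603, n = 2 per group), Ccdc39 by 7.69 (SE 0.33), Osbpl9 by 7.28 (SE 0.59) and Dazl by 7.10 (SE 0.38). Hoxa5 fell by 7.41 (SE 0.37), Dus2 by 7.29 (SE 0.44) and Acp1 by 6.58 (SE 0.66), with -2.43, -2.33 and -1.59 on the hybridization scale. Of the piRNA pathway genes, 13 of 22 rose and 1 fell (16 and 1 adjusted over the list alone), Ddx4 by 6.21 (SE 1.31) and Mael by 5.47 (SE 1.59, adjusted p = 0.0432). In the pachytene list 19 of 35 rose and 2 fell (22 and 2 adjusted over the list alone), in the round spermatid list 13 of 34 rose and 0 fell (12 and 0 adjusted over the list alone), and in the axoneme list 36 of 74 rose and 1 fell. Acrv1, an acrosomal gene, rose by 6.04 (SE 0.96) and Sycp2 by 6.40 (SE 0.68). The camera adjusted p was 0.000121 for the piRNA pathway, 3.70e-05 for pachytene, 3.74e-05 for round spermatid and 4.01e-08 for axoneme genes. With an estimated correlation these became adjusted p = 0.156, 0.156, 0.627 and 0.156.

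Chaperone genes (18 rose and 2 fell of 40, 18 and 3 adjusted over the list alone) and ubiquitin genes (43 rose and 17 fell of 156, 42 and 17 adjusted over the list alone) passed camera in shCaf1 (adjusted p = 0.000142 and 0.0326, and adjusted p = 0.406 and 0.162 with an estimated correlation). The elongating spermatid list also passed upward, with 3 of 32 risen and 2 fallen (1 and 1 adjusted over the list alone; camera adjusted p = 0.0326, and adjusted p = 0.685 with an estimated correlation), and Akap4, a fibrous sheath gene, rose by 4.74 (SE 1.32, adjusted p = 0.0386). Without control replicate 1 its median relative to all genes turned from 2.25 to -0.53 and the call ended. Glycolysis genes (5 rose and 1 fell of 21, 4 and 0 adjusted over the list alone; camera adjusted p = 0.0428, and adjusted p = 0.685 with an estimated correlation) turned in the same way from 1.88 to -0.091. Interferon response genes fell in 6 of 16 cases and endothelial genes in 5 of 8, with the same counts adjusted over the list alone (camera adjusted p = 0.0326 and 0.0428, and adjusted p = 0.491 and 0.406 with an estimated correlation), and each of these falls turned to a rise on the hybridization scale, as did 95.6% of all lower calls. Eng, an endothelial receptor, moved from -2.81 to 1.73, and the antiviral gene Oas1a from -3.63 to 0.93. Ribosomal protein genes had 14 falls and 4 rises of 47 (14 and 3 adjusted over the list alone) and did not pass camera (adjusted p = 0.0728). Of the 22 CCR4-NOT genes 4 rose and 10 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.447), and 9 of these falls turned to a rise on the hybridization scale. Among 37 decapping and decay genes 5 rose and 8 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.739).

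**Figure D3:**
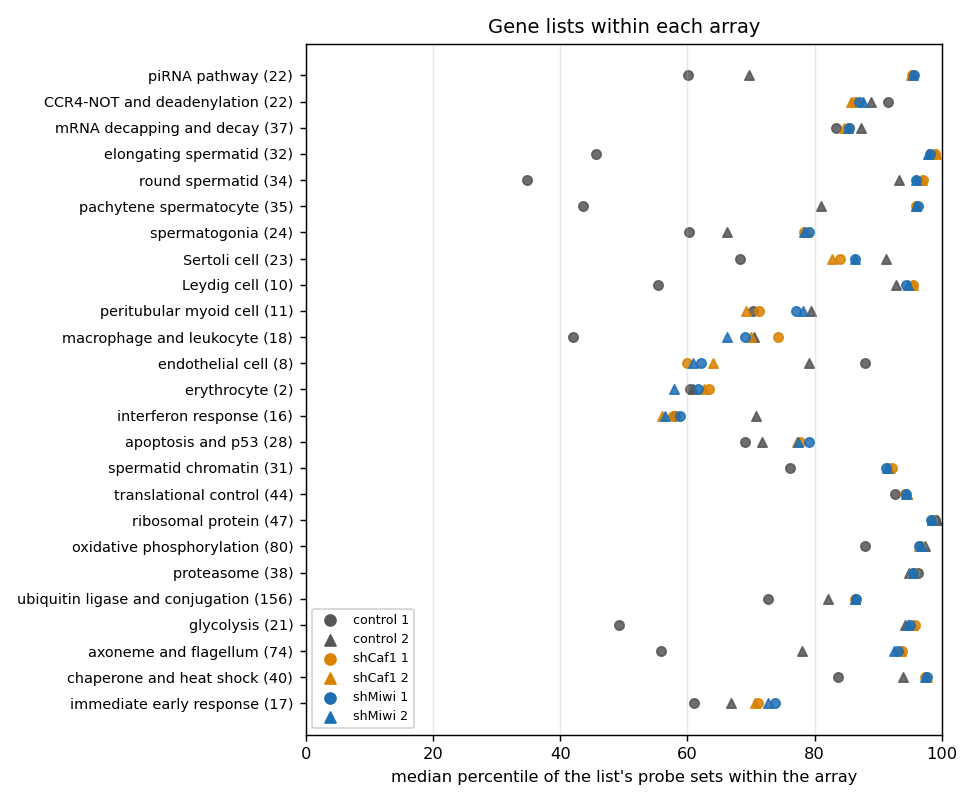
Median percentile of each gene list's probe sets within each array (number of genes in brackets), 1 point per array, circles for replicate 1 and triangles for replicate 2. The elongating spermatid list lies at 45.6 on control 1 and 98.0 on control 2, and the piRNA pathway list at 60.1 and 69.8 on the controls and between 95.2 and 95.6 on the shRNA arrays.

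In total, limma called 11205 probe sets in shCaf1 against control, 4186 higher and 7019 lower, from 7380 named genes. The split became 5273 and 3807 with quantile normalization, 5653 and 5459 with median centring, and 24720 and 9 with hybridization control scaling, which moved the median difference from -0.25 to 3.15. Of the lower calls, 95.6% turned higher under that common shift and 97 stayed lower than each control array on both scales. The count was 21205 without control replicate 1, 22675 without control replicate 2, 5899 and 5896 without shMiwi replicate 1 and 2, and 0 without either shCaf1 array. The size rule gave 16533 probe sets against 2711 and 2400 in the other splits, which are again no measure of chance.

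The log2 differences of shMiwi and shCaf1 from control correlated across probe sets at Pearson's r = 0.982 and Spearman's rho = 0.983. Unchanged groups simulated against the same control arrays gave r = 0.963 and rho = 0.907, so sharing the controls alone gives a correlation of nearly this size. The covariance was 4.98 against 1.06 simulated. Calls in both comparisons numbered 3969 higher and 6508 lower, and 1 probe set was called in opposite directions. With a different control array for each comparison, a split chosen after the data were seen, r was 0.679 (rho = 0.694) with shMiwi against control 1 and 0.633 (rho = 0.653) the other way, with covariances of 3.99 and 3.85.

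Direct comparison of shMiwi with shCaf1 does not use the control arrays' means. In the fit on all 6 arrays, limma called 0 of 27022 probe sets, with 264 at an unadjusted p under 0.05, and 1393 without control replicate 1 or 1528 without control replicate 2. Camera called the elongating spermatid and axoneme lists lower in that fit (adjusted p = 0.0471 for both, and adjusted p = 0.894 and 0.827 with an estimated correlation). In the fit on the 4 shRNA arrays alone, limma called 1981, of which 1030 were higher and 951 lower in shMiwi. The values that follow are from the 4 arrays. Camera on these arrays was not among the tests fixed before the data were examined.

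The tissue kallikrein genes Klk1b27 and Klk1b24 were higher in shMiwi by 3.91 (SE 0.23, adjusted p = 0.000178, n = 2 per group) and 3.86 (SE 0.15, adjusted p = 2.21e-05), and Klk1b24 read 1976 and 1953 in shMiwi against 118 and 122 in shCaf1. Klk1b21 was higher by 2.98 (SE 0.31) and Col4a4, a basement membrane collagen, by 1.94 (SE 0.18). Afm was lower by -3.35 (SE 0.23, adjusted p = 0.000419), Tmprss11a by -3.00 (SE 0.27), Hoxd10 by -2.69 (SE 0.24) and Dus2 by -2.53 (SE 0.37). Ptgds, a prostaglandin D synthase in the Leydig cell list, was lower by -2.45 (SE 0.11, adjusted p = 4.88e-05).

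Of the 32 elongating spermatid genes, 20 were lower and 0 higher in shMiwi than in shCaf1 (24 and 0 adjusted over the list alone), with a median log2 difference of -0.58 (SD 0.32 over genes). Spata18 was lower by -1.23 (SE 0.11, adjusted p = 0.00125), Fscn3 by -1.08 (SE 0.14) and Akap4 by -0.98 (SE 0.11). Camera gave adjusted p = 2.28e-16 with the preset correlation, and adjusted p = 0.552 with an estimated correlation. Of 34 round spermatid genes 8 were lower and 0 higher (20 and 2 adjusted over the list alone), led by Actl9 at -0.94 (SE 0.12), and the median was -0.35. The pachytene list had 3 lower genes and 0 higher of 35 (7 and 1 adjusted over the list alone), a median of -0.05 and no camera call (adjusted p = 0.222). Lower by camera were also axoneme genes (13 lower and 1 higher of 74, 17 and 1 adjusted over the list alone; adjusted p = 2.20e-05), ribosomal protein genes (10 and 0 of 47, 16 and 0; adjusted p = 1.04e-05), glycolysis genes (6 and 1 of 21, 9 and 3; adjusted p = 0.0183), oxidative phosphorylation genes (2 and 3 of 80, 14 and 4; adjusted p = 0.00303) and chaperone genes (7 and 0 of 40, 7 and 0; adjusted p = 0.00363). For these lists and for round spermatid genes (camera adjusted p = 6.77e-06) the estimated correlation gave adjusted p = 0.552. Among 10000 random lists matched on brightness, a test chosen after the data were seen, a median as low came in 23.1% for ribosomal protein, 17.4% for oxidative phosphorylation, 20.3% for chaperone, 4.80% for glycolysis, 0.240% for axoneme and 0% for round spermatid genes. The ribosomal protein, oxidative phosphorylation and chaperone lists were thus not set apart from other genes of their brightness. Hk1, the first enzyme of glycolysis, was lower by -1.02 (SE 0.13) and Gapdhs, its sperm-specific enzyme, by -0.87 (SE 0.12).

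Genes of 2 somatic cell lists were higher in shMiwi. In the Sertoli cell list 5 of 23 were higher and 0 lower (7 and 0 adjusted over the list alone; camera adjusted p = 0.0326), led by Inhbb at 0.98 (SE 0.13), and in the peritubular myoid list 4 of 11 were higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.0312), with Myl9 at 0.94 (SE 0.14) and Myh11 at 0.93 (SE 0.17). The estimated correlation gave adjusted p = 0.552 for both. In the macrophage list 1 gene was higher and 2 were lower (2 and 5 adjusted over the list alone), with Mrc1 at 0.69 (SE 0.13) and H2-Aa at -1.87 (SE 0.19). The piRNA pathway list had 1 higher and 2 lower genes of 22 (4 and 5 adjusted over the list alone), with Mybl1, a transcription factor of pachytene piRNA loci, at 0.80 (SE 0.17) and Piwil1 among the lower. In the CCR4-NOT list Cnot6 alone passed, at 0.58 (SE 0.13, adjusted p = 0.032; 5 higher and 3 lower adjusted over the list alone). Neither list passed camera (adjusted p = 0.896 for both).

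**Figure D4:**
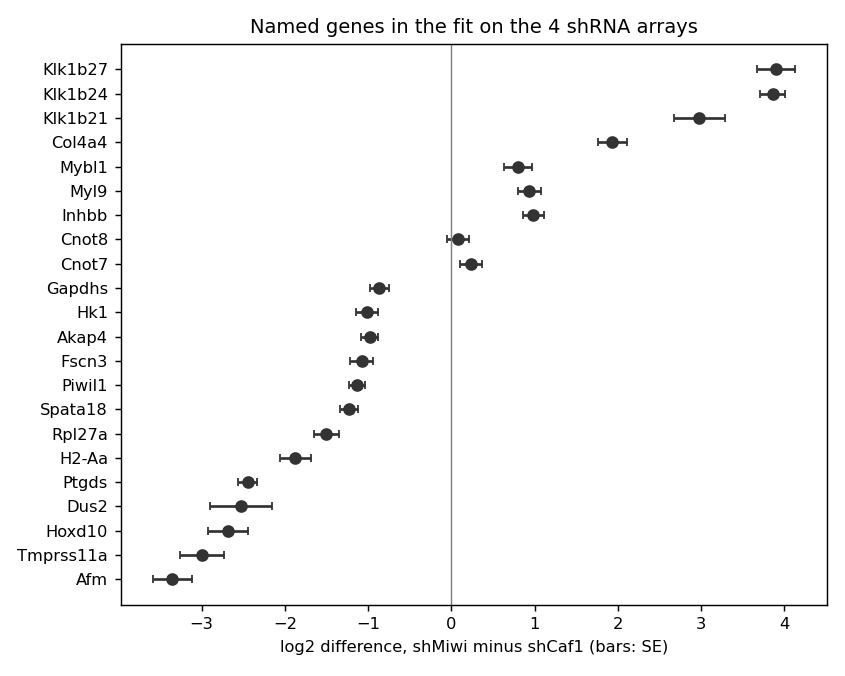
Log2 difference of shMiwi minus shCaf1 for named genes, with the SE of the limma fit on the 4 shRNA arrays (2 arrays per group). Klk1b27 and Klk1b24 lie at 3.91 and 3.86, Piwil1 at -1.14, and Afm at -3.35.

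The count of 1981 fell to 15 with eBayes without an intensity trend, and ranged from 276 without shCaf1 replicate 2 to 3878 without shMiwi replicate 1, with 794 without shCaf1 replicate 1. Median centring split the calls into 577 higher and 1097 lower, and hybridization control scaling, which moved the median of all probe sets from 0.02 to 0.38, into 7047 higher and 257 lower. On that scale the elongating spermatid median was -0.18 and the round spermatid median 0.05, and the medians of the other lists called lower turned above 0 (axoneme 0.21, ribosomal protein 0.18, glycolysis 0.18, oxidative phosphorylation 0.24 and chaperone 0.22), below the 0.38 of all probe sets. Relative to all genes, the glycolysis and chaperone lists also turned with quantile normalization (0.0093 and 0.031). Poly-A spike-in controls relative to the hybridization controls were higher on replicate 2 in both shRNA groups (log2 -4.49 and -2.91 in shCaf1, -5.27 and -3.22 in shMiwi). The same log2 value was -0.56 on control 1, above all other arrays, and -4.08 on control 2. The source of the high value on control 1 was not tested.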

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

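The tests in this part were all chosen after the values they use had been seen. Outlier tests need at least 4 arrays in a group and were not run. Among the Affymetrix control probe sets, which enter no comparison, the middle beta-actin probe set was brighter on all 4 shRNA arrays than on both control arrays, at 1.42-fold of the mean control signal.

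For the many calls against control, an array's scaling factor as the whole cause, or a smaller labelled amount of the same RNA, predicts a constant ratio among bright probe sets. Among 1525 with a mean shRNA signal over 5000, the SD of log2 control over shRNA was 2.50 for control 2 and 3.32 for control 1, against 0.310 and 0.569 between shRNA replicates at the dimmed level and 0.291 between shMiwi and shCaf1, which argues against both on both arrays. Whether the transcripts called lower fell in amount stays open, because hybridization scaling moves all probe sets the same way and turns most of these differences. An effect of the vectors stays open and untested, because every control array differs from every shRNA array in quality, the 3' to 5' ratios of Actb and Gapdh included, as well as in vector; RNA integrity was not tested as a cause.

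Spermatid transcripts were low on control 1, where Prm3 lay at percentile 34.04 against 99.4 on control 2, and the design gives no biological explanation for a difference between control replicates. A mix with all 5 somatic cell types in excess would raise all 5 somatic lists. The Leydig list lay -39.7 percentile points from its shRNA mean while the endothelial list lay 26.1 points above. On the sorted shRNA arrays the Leydig list already stood between 94.4 and 95.5 and the Sertoli list between 82.7 and 86.4. A fall from there need not measure those cells, and a mix of fewer types was not tested, so this does not decide. Of 13 endothelial genes on the array, 8 passed the filter, whose mean includes the control arrays, so genes bright only there could pass. For endothelial cells alone 5 of these 8 genes lay above all shRNA arrays and Vwf, Tek and Cldn5 did not. The shift of 26.1 leaves that source open. This test was first set to be met by any 1 of the 5 lists and was divided after its result was seen. GFP is carried by the vectors and marks transduced cells, and whether the sort removed somatic cells was not tested. For RNA that is not of a rodent, the B2 repeat probe set lay -74.8 percentile points from its lowest value on the other arrays. This cannot decide, because most transcripts bright on the shRNA arrays were dim on control 1. After hybridization scaling 101 probe sets exceeded 1000 there, against 5980 to 8137 on the shRNA arrays. Control 1 also shares 63 of its 100 brightest probe sets with control 2, where that repeat is bright. The mouse Cnot7 and Piwil1 probe sets also ranked 1st and 4th on control 1.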

How the results depend on the processing

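Alternatives for the fit on the 4 shRNA arrays, hybridization scaling of gene lists and separate controls for the correlation were chosen after seeing the data, and the other alternatives were planned. Where a cause is not named, it was not tested.

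For shMiwi and shCaf1 against control, the counts were 5819 and 5588 with 1 probe set per gene and 6793 and 6448 with the filter at the 60th percentile, where fewer probe sets were tested. They were 18076 and 17244 without a filter, 6632 and 5941 with only the arrays of the groups compared, and 25421 and 24729 with hybridization scaling. Leaving out 1 array gave 0 to 22700 for shMiwi and 0 to 22675 for shCaf1. The upper values come from fits in which a lone control array is assumed to vary like the shRNA arrays, which the spread between the controls contradicts. The 2-fold counts were 10548 and 10326 at the 60th percentile, 29581 and 29048 without a filter, and 25690 and 24974 with hybridization scaling. The correlation of the differences ranged from 0.972 to 0.988 under 14 alternatives, and was 0.679 and 0.633 with a different control array for each comparison, which removes the shared array.

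For shMiwi against shCaf1 on 6 arrays the count of 0 became 6 with hybridization scaling and 1981 with the 4 arrays alone, and 0 to 1528 on leaving out 1 array. In the 4 arrays the 1981 became 3689 at an adjusted p under 0.10, 15 without trend, 568 without a filter, 7304 with hybridization scaling, and 276 to 3878 on leaving out 1 array.

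Lists past the camera threshold, 7 for shMiwi, 10 for shCaf1 and 9 between them, became 0, 0 and 0 with an estimated correlation and 4, 5 and 5 with hybridization scaling. Without a filter shMiwi had 12, with quantile normalization shCaf1 had 5 and the comparison between them 4, and leaving out 1 array gave 4 to 10 there.

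Piwil1 in shMiwi against control was -0.62 with hybridization scaling and -7.16 to -4.86 on leaving out 1 array, and in shCaf1 0.12 and -6.03 to -3.72. Cnot7 was -2.28 in shCaf1 and -1.65 in shMiwi with hybridization scaling, and -8.97 to -5.57 and -8.74 to -5.33 on leaving out 1 array. Between the vectors Piwil1 kept -1.14 but passed with the 4 arrays alone, and did not pass in them without trend (-1.14, adjusted p = 0.133). It was -1.18 to -1.09 on leaving out 1 array. Cnot7 passed at 0.63 with hybridization scaling, which moved the median of all probe sets to 0.38.

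With hybridization scaling these genes turned to a rise in shMiwi and shCaf1: Cnot2 (0.12 and 0.051), Des (1.79 and 2.10), Egfl7 (1.33 and 1.03), Eng (1.95 and 1.73), Hba-a2 (1.21 and 1.04), Laptm5 (1.88 and 1.78), Oas1a (0.56 and 0.93), Psmb7 (0.38 and 0.53) and Rsad2 (0.92 and 0.34). Atp5g3 (0.23), Car4 (1.18) and Egr3 (0.72) did so in shMiwi, and Klf6 (2.24) in shCaf1. Values of lists are medians relative to the median of all genes. By that measure the ribosomal list in shCaf1 turned to 0.12 with hybridization scaling. The elongating spermatid list in shCaf1 ranged from -0.53 to 4.65 and glycolysis from -0.091 to 4.14 on leaving out 1 array. With quantile normalization glycolysis (0.0093) and chaperone genes (0.031) turned between the vectors.

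With the replicate number as a block, the counts were 10400 and 9851 against control, 0 between the vectors on 6 arrays and 5458 on 4, the last chosen after seeing the data. The deviations of same-numbered arrays correlated at 0.06, 0.004 and 0.18, and the labels link same-numbered arrays only by the number. In both shRNA groups replicate 2 had the higher poly-A value and the higher Actb 3' to 5' ratio. That ratio was 4.69 against 2.87 in shCaf1 and 3.01 against 2.05 in shMiwi. A shared batch was not tested. The median signal after hybridization scaling was 3.71 and 13.3 on the control arrays, against 61.0 to 87.7 on the shRNA arrays.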

Other observations

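Of the tests of causes in this part, all but that on bright probe sets were chosen after the result was seen. The limma fits, the gene lists and the camera tests with the preset correlation were set before the data were examined. The genes in this first paragraph were chosen after their values were seen, apart from Klk1b21, Klk1b24, Klk1b27, Col4a4, H2-Aa and Ptgds. In the 4 arrays Col3a1 was higher in shMiwi than in shCaf1 by 1.93 (SE 0.12, adjusted p = 0.000229), with 4863 and 4342 in shMiwi against 1206 and 1188 in shCaf1, and Col1a2 by 1.87 (SE 0.15, adjusted p = 0.000855). Of the 10 probe sets of 5 collagen genes examined, 9 were higher and 1, of Col4a4, did not pass (0.51, adjusted p = 0.282); no list of matrix genes was tested. Among major histocompatibility genes, 3 of the 8 probe sets of H2-D1 were higher and 3 lower, from -3.90 (SE 0.27, adjusted p = 0.000368) to 1.29 (SE 0.17, adjusted p = 0.0063), and the 3 probe sets of H2-Aa were lower by -1.79 to -2.57, while the 2 of H2-Ab1 and the 4 of H2-K1 did not pass. The mice were of an outbred strain and the animals behind each array are not known. Differences between animals thus cannot be told apart from differences between vectors. Both Ptgds probe sets were lower, by -2.45 and -2.74. Of the 10 probe sets of 7 kallikrein genes examined, those of Klk1b21, Klk1b24 and Klk1b27 were higher and 7 did not pass, of Klk1, Klk1b5, Klk1b8 and Klk1b16, with differences from -0.77 to 0.09. On the hybridization scale these values were 2.32 for Col3a1, 2.26 for Col1a2, -3.63 and 1.67 for H2-D1, -1.44 to -2.23 for H2-Aa, and -2.05 and -2.34 for Ptgds; among the 8 H2-D1 probe sets 1 that did not pass turned from -0.14 to 0.15.

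On control 1 the brightest probe set of the array was that of Cnot7 (2003570), and the other Cnot7 probe sets ranked 2nd and 6th, at 1491010 and 1377500. Piwil1 ranked 4th there, at 1445360. On the same array the germ cell transcripts Tnp1 and Ldhc read 39 and 82, against 82532 and 112941 on control 2. The Cnot7 and Piwil1 signals of control 1 are thus no sure baseline for a knockdown. On control 2 the Cnot7 probe sets that ranked 2nd and 6th on control 1 read 9118 and 10262.

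Lists not described above showed no camera call against control in either comparison. In shMiwi against control, higher and lower genes numbered 5 and 4 of 24 for spermatogonia, 5 and 4 of 23 for Sertoli, 3 and 0 of 10 for Leydig, 3 and 2 of 11 for myoid and 5 and 2 of 18 for macrophage genes. They numbered 0 and 1 of 2 for erythrocyte, 10 and 7 of 28 for apoptosis, 8 and 4 of 31 for spermatid chromatin, 9 and 8 of 44 for translational control, 8 and 8 of 80 for oxidative phosphorylation, 4 and 8 of 38 for proteasome, and 1 and 3 of 17 for immediate early genes.

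The elongating spermatid list was lower in shMiwi than in shCaf1 by camera with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.552 in the 4 arrays), and its median of -0.58 became -0.18 on the hybridization scale. A lower share of all germ cells would lower the pachytene list alike, but the elongating median lay -0.53 from the pachytene median (32 and 35 genes, permutation p = 3e-05 over genes, which are not independent replicates). A difference for bright probe sets in general, as the whole cause, is argued against by 0% of 10000 random lists matched on brightness having a median as low; their median was -0.19 and the lowest -0.37, so brightness goes with part of the difference. In the same arrays the Sertoli and myoid lists were higher (camera adjusted p = 0.0326 and 0.0312, and 0.552 for both with an estimated correlation), as were 9 of the 10 collagen probe sets. Other somatic lists were not: the macrophage list had 1 higher and 2 lower genes of 18, the Leydig list 1 and 1 of 10, and the endothelial list 0 and 0 of 8. A shift between spermatid stages in the sorted cells, more somatic cells beside a change of stage, and an effect of either vector may each account for the lower elongating spermatid list. They were not tested.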
